A study of Homo sapiens with 8 samples.

How the data were processed

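The series holds RNA sequencing of NB4 cells in 4 groups, shScr vehicle, shScr ATRA, shTFEB vehicle and shTFEB ATRA, with 2 samples per group in the labels. Per the labels' protocols, hairpins were delivered by lentivirus, cells were treated with 1 µM ATRA or ethanol for 72 h, and total RNA was taken up in TruSeq libraries. The titles of both shScr ATRA samples carry the word vehicle as well, and their group was taken from the treatment field. Wild-type NB4 cells of the design were not analysed here.

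The FPKM values were made by the authors before they were deposited: per the submitters' processing notes, reads were aligned to hg19 with TopHat and expression was estimated with Cufflinks and Cuffdiff, whose versions the sources used here do not give. Each of the 4 deposited tables lists 65986 transcript models with 1 FPKM, a lower and an upper bound and a status, and how the 2 samples were combined is not stated. The models comprise 43835 RefSeq models, 21434 assembled models without a symbol and 717 other small RNA models. Gene symbols came from a RefSeq gene table of assembly GRCh38.p14, used for names alone, in which 39841 of 41159 RefSeq accessions were matched (96.8%); coordinates are the hg19 coordinates of the files, counted from 1.

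FPKM were summed over the models of a symbol, which gave 22627 symbols, and no further normalisation was applied. Bounds of a gene are likewise sums of the deposited bounds of its models. Genes with a mean over the 4 groups of at least 1 FPKM (11052) entered the comparisons, as log2((FPKM + 1)/(FPKM + 1)). With 1 value per group no test was possible, so genes at least 2-fold apart (log2 ratio of 1 in size) were counted. The 5 comparisons were ATRA against vehicle in each cell line, shTFEB against shScr under each treatment, and the difference of the 2 responses. Named genes were TFEB, TFE3, MITF and TFEC, the 10 largest rises and falls per comparison among genes with at least 5 FPKM in a compared group, and up to 4 members per gene list with the largest change. Some genes that this rule names are not reported here. Symbols at several loci, small RNAs and names starting with LOC or LINC or containing -AS were left out of that ranking. Pseudogenes with other names, such as NSUN5P2 and SBDSP1, stayed in it. The comparisons, this rule, 25 gene lists and the alternatives were set before the data were examined, except where stated. Many ranked genes turned out to be listed at 0 in a compared group, so a ranking of genes above 0 and further list members were added after the values were seen.

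The lists covered lysosomal hydrolases, lysosomal membrane, V-ATPase, autophagy, MiT/TFE factors with mTORC1 sensing, the retinoic acid response, neutrophil maturation, promyelocyte granule and progenitor genes, monocyte and macrophage markers, cell cycle, MYC with ribosome biogenesis, interferon-stimulated genes, chemokines and cytokines, the integrated stress response, immediate-early and heat shock genes, cholesterol synthesis, lipid handling with NADPH, apoptosis, myeloid surface receptors and adhesion, lymphoid, erythroid with megakaryocytic and non-blood markers, reference, mitochondrially encoded and core histone genes. The median log2 ratio of a list was placed among 10000 random lists of the same size drawn from 10 bins of mean expression, which describes these libraries and is not a p-value. A list of eosinophil, basophil and mast cell genes was added after the values were seen.

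Relative depth was read from the ratios of values under 0.1 FPKM, which cluster at ratios of whole numbers up to 12 (tolerance 0.2%). Absolute depth was read from models with a locus of 920 to 980 bases, taken as intronless, whose value implied a depth within a preset window. In a model of 950 bases 1 fragment was worth 0.0172 FPKM in shScr vehicle, 0.0165 in shScr ATRA, 0.0147 in shTFEB vehicle and 0.0189 in shTFEB ATRA. The deposited bounds enclosed the FPKM in 77.5% to 80.4% of the models with status OK and at least 1 FPKM, so they were used as deposited and not as confidence intervals. Estimates had failed, or were skipped for too many fragments (EEF1A1), for 25 models, counted whether or not they had a symbol. The symbols of such models numbered 6, among them CELF2 and ZMYM2. They were kept, as were 1250 small RNA symbols.

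Alternatives were pseudocounts of 0.1 and 5 FPKM, no filter on low values, a mean of at least 5 FPKM, median-of-ratios and upper-quartile rescaling, the highest model in place of the sum, models with status OK alone, and intervals that do not overlap. Leaving out small RNA symbols, symbols with failed estimates or genes listed at 0 in any group, using midpoints of the deposited intervals, and taking ratios of interferon-stimulated genes without a pseudocount, were added after the data were seen. The calculation was tested on simulated data for ATRA against vehicle in shScr cells: of 200 genes changed by known amounts among 11052, 99.5% passed the 2-fold mark, and 0 of 10852 unchanged genes did. The simulation drew counting noise alone around the shScr vehicle values. The changed genes had at least 5 FPKM and were changed by more than 2-fold. It thus checks the calculation and does not measure false calls between unreplicated groups. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.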

Results

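RNA was sequenced from NB4 cells, a human acute promyelocytic leukaemia line that carries the PML-RARA fusion and matures towards granulocytes when exposed to all-trans retinoic acid (ATRA). The cells expressed either a short hairpin RNA against TFEB (shTFEB), a transcription factor of lysosome and autophagy genes, or a scrambled hairpin (shScr), and received ethanol vehicle or 1 µM ATRA for 72 h. The labels give 4 groups of 2 samples, 8 in all. The deposited tables hold 1 value per transcript model and group, in FPKM, which scales fragments to model length and to the mapped fragments of the group. The spread between samples could therefore not be computed, no test was run and no p-value is given: each difference below is the size of a ratio between groups without a replicate check. From the spacing of the lowest values, the depth relative to shScr vehicle was 1.05 for shScr ATRA, 1.17 for shTFEB vehicle and 0.911 for shTFEB ATRA. That corresponds to roughly 61.2 M fragments (M, mega) in shScr vehicle, 63.8 M in shScr ATRA, 71.6 M in shTFEB vehicle and 55.8 M in shTFEB ATRA. This approximation rests on 4 to 17 short models per group, taken as intronless from their length. Only models that implied a depth within a preset window were kept, which bounds these absolute values. A total of 11052 genes had a mean of at least 1 FPKM over the 4 groups and were compared. A gene is said to have risen or fallen where its log2 ratio, taken after adding 1 FPKM to both values, reached 1 in size, which is a 2-fold mark of size and not a test.

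The targeted gene was examined first. TFEB mRNA (hg19 chromosome 6, 41651716 to 41703997, 5 models) stood at 1.203 FPKM in shScr vehicle and 19.4 FPKM in shScr ATRA. The deposited bounds, summed over these models, ran from 0.928 to 1.52 and from 17.9 to 20.9. The groups labelled shTFEB held 1.35 FPKM under vehicle (1.11 to 1.63) and 8.44 FPKM under ATRA (7.41 to 9.51). TFEB was thus 2.30-fold lower in shTFEB than in shScr cells under ATRA, at 43.6% of the shScr level, with bounds that do not overlap. Under vehicle the group labelled shTFEB was not lower: the ratio was 1.13 and the bounds overlapped, so the label of that group is not borne out by TFEB mRNA, and the group is called "labelled shTFEB" where it is compared below. ATRA raised TFEB 16.1-fold in shScr and 6.23-fold in shTFEB cells. Its relative TFE3 went from 7.16 to 19.9 FPKM in shScr cells and from 7.88 to 16.0 FPKM in shTFEB cells, a log2 ratio of 1.35 against 0.94. MITF stayed between 0.0519 and 0.309 FPKM, and TFEC between 0 and 0.356 FPKM, in the 4 groups.

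**Figure D1:**
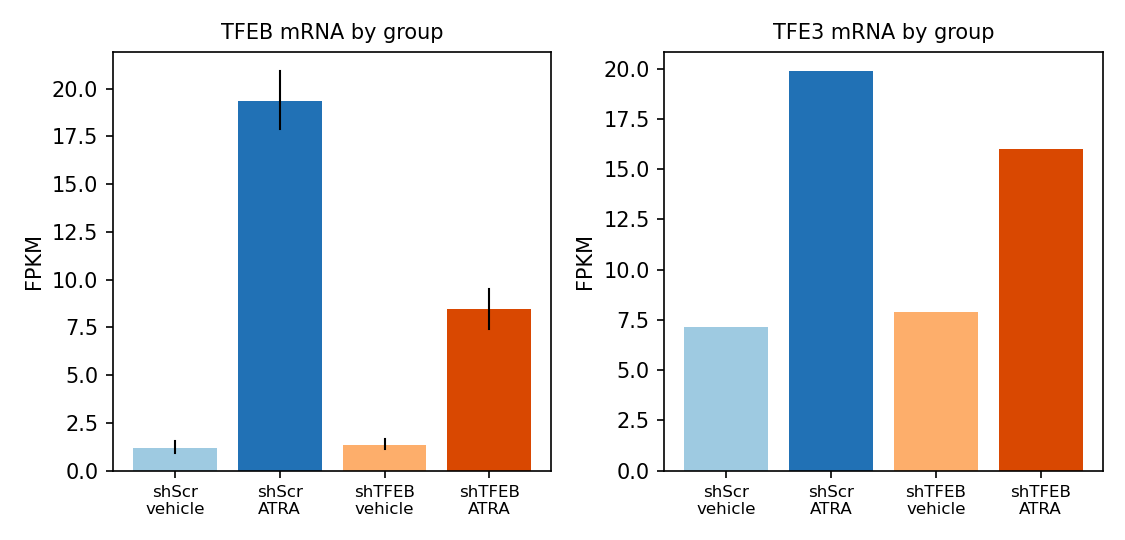
Bars give TFEB and TFE3 mRNA in FPKM (y axis, from 0) for the 4 groups, 1 value each, summed over the models of the gene. Black lines on TFEB give the deposited lower and upper bounds, summed likewise. No bounds are drawn for TFE3, whose ATRA values lay above its upper bounds. TFEB reached 19.4 FPKM in shScr ATRA and 8.44 FPKM in shTFEB ATRA, against 1.203 and 1.35 FPKM under vehicle.

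Cells with the scrambled hairpin gave the reference response to ATRA. ALOX5AP, the lipoxygenase-activating protein of leukotriene synthesis, went from 1.21 to 1262 FPKM (log2 ratio 9.16), the transglutaminase gene TGM2 from 4.08 to 2091 FPKM, and the chemokine genes CCL2 and CCL24 from 2.75 to 1488 and from 0.493 to 384 FPKM. S100A8 (log2 ratio 7.97), the bactericidal protein gene BPI (7.62) and the lipolysis inhibitor gene G0S2 (7.42) followed. NCF1, NCF1B and NCF1C also reached log2 ratios of 8.43 to 8.67, but they are near-identical copies whose fragments the counting could have split, so their separate values are uncertain. CYTL1 had the largest fall, from 188 to 0.262 FPKM, followed by the cystatin gene CST7, from 128 to 0.557 FPKM. SPNS3 and MS4A3 had log2 ratios of −4.35 and −4.30. The other 6 of the 10 largest falls (PPAN, PAM16, GPN1, AIMP2, SLMO2-ATP5E and CTSW) belong to genes that are listed at 0 under ATRA, for which no fold is given. Among genes above 0 in both groups, MTSS2 came next (−4.11), then the intermediate filament gene VIM, from 308 to 17.5 FPKM. DEFB1, PRSS57 and IGFBP4 followed.

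The gene lists followed the same course in shScr cells. Of 26 compared genes of the retinoic acid response, 19 rose and 2 fell, with a median log2 ratio of 3.21 that exceeded all 10000 random lists of the same size and expression. ASB2 went from 0.322 to 147 FPKM, and the retinaldehyde reductase gene DHRS3 from 0.553 to 100.2 FPKM. Neutrophil maturation genes rose in 26 of 32 cases and fell in 3 (median 1.99), with the integrin gene ITGAM going from 2.18 to 83.1 FPKM and the NADPH oxidase gene CYBB from 48.7 to 966 FPKM. Surface receptors and adhesion genes of myeloid cells rose in 23 of 31 cases and fell in 1 (median 1.90), led by ICAM1 with a log2 ratio of 7.35. Monocyte and macrophage markers, of which 9 of 22 were expressed highly enough to be compared, rose in 6 cases and fell in 1, with CX3CR1 at a log2 ratio of 5.20. Chemokine and cytokine genes rose in 15 of 23 cases, and TNF fell. Interferon-stimulated genes rose in 28 of 38 cases and fell in none (median 2.87), led by OAS3, OAS1 and IFI6. In contrast, 15 of 22 promyelocyte granule and progenitor genes fell and 2 rose (median −2.08): MPO, the granule peroxidase, went from 3871 to 662 FPKM and the eosinophil major basic protein gene PRG2 from 1094 to 69.8 FPKM. MYC fell from 279 to 25.6 FPKM, and 25 of the 27 genes of the MYC and ribosome biogenesis list fell (median −1.77). Cell cycle genes fell in 11 of 39 cases and rose in 3 (median −0.71), with MCM4 and MCM6 the members that fell furthest and the inhibitor genes CDKN1A and CDKN2D and the cyclin gene CCND1 the 3 that rose.

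Lysosome and autophagy genes, the classes that TFEB is known to control, also moved up with ATRA in shScr cells. Of 38 lysosomal hydrolase genes 22 rose and none fell, with a median log2 ratio 1.35 above that of all genes. The cathepsin gene CTSD went from 43.1 to 1830 FPKM, and FUCA1, SMPD1 and PSAP had log2 ratios of 2.70, 2.46 and 2.27. Lysosomal membrane genes rose in 9 of 24 cases, with CD68 at 2.77, and ABCA2 fell. V-ATPase genes rose in 4 of 18 cases (median 0.62), TCIRG1 most with 2.24, and autophagy genes in 13 of 42 cases (median 0.30), SQSTM1 most, from 21.6 to 164 FPKM. The medians of all 4 lists lay above at least 99.8% of the random lists. Of the 24 MiT/TFE and mTORC1 genes only TFEB and TFE3 rose and MLST8 fell. Apoptosis regulators rose in 13 of 26 cases, among them BCL2A1 from 2.37 to 380.2 FPKM, whereas BCL2 fell from 21.3 to 0.501 FPKM. Immediate-early and heat shock genes rose in 9 of 17 cases and fell in 2 (HSP90AA1 and HSPH1). Lipid handling and NADPH genes divided into 7 that rose, with PGD at 3.02, and 4 that fell, with NR1H3 listed at 0 under ATRA. The integrated stress response list (17 genes) held 4 that fell, SLC7A5 furthest with −3.10, and 2 that rose. Among 23 cholesterol synthesis genes 2 rose, STARD4 with a log2 ratio of 1.09, and none fell, and their median of −0.12 became 0.01 after median-of-ratios rescaling.

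Markers of other cells gave few comparable genes: 4 of 19 lymphoid genes (2 rose, NKG7 and CD79A, and 2 fell), 3 of 20 erythroid and megakaryocytic genes (no member passed the mark) and 7 of 17 non-blood genes (2 rose and 2 fell, VIM among the latter). Histone genes rose in 5 of 7 cases. Of 14 reference genes B2M rose (1.43), HPRT1 fell (−1.16) and the other 12 did neither. These 12 include EEF1A1, which had too many fragments to be estimated in either shScr group, so its ratio was not measured. None of the 13 mitochondrially encoded genes could be compared, since the tables list no model on the mitochondrial genome. In total 1384 genes rose and 1676 fell under ATRA in shScr cells, 45.2% of the marked genes being higher. The median log2 ratio of all genes was −0.15, and rescaling by median-of-ratios or upper-quartile factors shifted it by 0.17 or 0.15. Relative to the median of all genes the retinoic acid list stood at 3.35 and the MYC and ribosome biogenesis genes at −1.62. The rescaled splits were 1637 higher and 1229 lower genes (57.1% higher) and 1600 higher and 1276 lower (55.6%), and with a pseudocount of 5 FPKM the counts dropped to 873 and 949.

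The retinoid response of shTFEB cells shared leading genes with that of shScr cells. TGM2 went from 2.23 to 1258 FPKM, ALOX5AP from 1.92 to 1031 FPKM and CCL24 from 0.630 to 413 FPKM. CCL2 and G0S2, leading genes of shScr cells, rose less in shTFEB cells, with log2 ratios of 6.38 and 5.92 against 8.63 and 7.42. Other genes entered the 10 largest rises: CLC, which encodes the Charcot-Leyden crystal protein of eosinophils and basophils, went from 1.58 to 771 FPKM (0.120 to 74.2 FPKM in shScr cells, a larger fold without the added 1 FPKM, 619.6 against 487), and the interferon-stimulated genes OAS3 and IFI6 reached log2 ratios of 8.17 and 7.63. EEF1A1 heads that ranking with 3139 FPKM under ATRA, but in the other 3 groups it is listed at 0 with the status for too many fragments to estimate, so it is not read as a change. CST7 (−5.38), VIM (−4.74), MTSS2 (−4.22), AHNAK (−4.01) and DEFB1 (−3.97) fell furthest among genes above 0, and SERF2, PAM16, AIMP2, CTSW and ASCC1 are listed at 0 under ATRA.

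By list, 37 of 38 interferon-stimulated genes rose in shTFEB cells with a median log2 ratio of 4.86, the largest median of the 24 lists that could be compared. Retinoic acid response genes rose in 21 of 26 cases and fell in 2 (median 3.08), and neutrophil maturation genes rose in 25 of 32 cases and fell in 2 (median 1.76). Monocyte and macrophage markers rose in 7 of 9 cases and fell in none (median 3.30), surface receptors and adhesion genes rose in 21 of 31 cases and fell in 2 (1.73), and chemokine and cytokine genes rose in 16 of 23 cases and fell in 1 (2.85). Lysosomal hydrolases rose in 20 of 38 cases and fell in none (1.01), lysosomal membrane genes rose in 9 of 24 cases and fell in 1 (0.66), V-ATPase genes rose in 3 of 18 (0.57) and autophagy genes in 8 of 42 (0.37). MYC and ribosome biogenesis genes fell in 22 of 27 cases (−1.28), promyelocyte genes fell in 14 of 22 cases and rose in 3 (−1.57), and cell cycle genes fell in 7 of 39 cases and rose in 1 (−0.54). Integrated stress response genes fell in 8 of 17 cases (−0.94), PHGDH and PSAT1 among them.

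Across shTFEB cells as a whole 1270 genes rose and 1159 fell, 52.3% of the marked genes being higher, around a median log2 ratio of −0.13 that rescaling shifted by 0.13 (median-of-ratios) or 0.06 (upper quartile). Relative to that median the interferon-stimulated list stood at 4.99 and the MYC and ribosome biogenesis genes at −1.15. After median-of-ratios rescaling the split was 1456 higher and 868 lower genes (62.7% higher), after upper-quartile rescaling 1335 and 1039 (56.2%), and with a pseudocount of 5 FPKM 795 and 582.

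Differences between the vehicle groups were small for most genes and large for a few. ITM2A stood at 0.820 FPKM in shScr vehicle and 26.1 FPKM in the group labelled shTFEB vehicle (31.8-fold higher), the paraoxonase gene PON2 at 0.133 and 11.8 FPKM (89.2-fold), the eosinophil peroxidase gene EPX at 5.78 and 82.8 FPKM (14.3-fold) and the histidine decarboxylase gene HDC at 10.4 and 96.1 FPKM (9.20-fold). All 4 were higher in shTFEB than in shScr cells under ATRA too: ITM2A 29.6-fold, PON2 109-fold, EPX 11.3-fold and HDC 13.1-fold. CYTL1 was lower, at 13.0 against 188 FPKM, as were DEFA1 and DEFA3 (1.81 against 25.2 and 1.76 against 23.3 FPKM), near-identical defensin genes whose separate values are uncertain. S100A9 (2.08 against 11.2 FPKM) and ROPN1L (log2 ratio −1.75) were lower as well. Most other genes of the fixed ranking are listed at 0 in a compared group: SERF2, NSUN5P2, NKIRAS2 and SRGAP2B in shScr vehicle, SLMO2-ATP5E, HCFC1R1, BBIP1 and CSTPP1 in the group labelled shTFEB vehicle. The 0 of CELF2 in shScr vehicle and of ZMYM2 in shTFEB vehicle is marked in the tables as a failed estimate. Without such genes, in a ranking made after the values were seen, GPX7, CCL2, LGALS3, PNMT, CHPF and the metallothionein gene MT1E came next among higher genes, with log2 ratios from 2.43 to 1.64. ART3, MS4A3, NAV3, IFI16 and H19 came next among lower genes, from −1.72 to −1.39.

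Gene lists moved little between the vehicle groups. None of the 38 lysosomal hydrolase genes passed the 2-fold mark (median log2 ratio 0.16, above 99.99% of the random lists), and of the 24 lysosomal membrane genes only CD68 passed it, with a log2 ratio of 1.05 (median 0.19). No V-ATPase, autophagy or MiT/TFE and mTORC1 gene passed the mark, at medians of 0.06, 0.08 and 0.03. Surface receptors and adhesion genes had a median of 0.34, above every random list, with no member past the mark. Promyelocyte genes had a median of −0.26, below every random list, with CST7 and MS4A3 lower and GATA2 higher, at 10.1 and 21.9 FPKM. Neutrophil maturation genes held 2 higher members, NCF4 and ITGAM, and 1 lower, S100A9. Interferon-stimulated genes stood at a median of 0.06, inside the range of the random lists, and IFI16 was the only member past the mark, at 7.01 and 1.97 FPKM. The added 1 FPKM draws low values together: without it, 9 of the 37 members above 0 in both vehicle groups were at least 2-fold higher in the group labelled shTFEB, such as OAS2 (0.0235 and 0.340 FPKM) and OAS1 (0.246 and 0.932 FPKM), and 1 was lower. Retinoic acid response (0.05), apoptosis (0.07) and lipid genes (0.05) held no member past the mark. Nor did the cell cycle and MYC and ribosome biogenesis lists, whose medians of −0.01 and −0.01 turned to 0.01 and 0.02 after upper-quartile rescaling and whose means were 0.04 and 0.01. Among erythroid and megakaryocytic genes GATA1 was higher, at 1.04 and 3.99 FPKM.

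Between the vehicle groups 117 genes were at least 2-fold higher and 87 at least 2-fold lower in the group labelled shTFEB, 1.85% of all genes compared. Counts this small moved with the handling of the values: leaving out small RNA symbols gave 67 and 45, leaving out genes listed at 0 in any group 56 and 37, a mean of at least 5 FPKM 67 and 52, intervals that do not overlap 72 and 50, a pseudocount of 5 FPKM 70 and 48, and a pseudocount of 0.1 FPKM 211 higher genes.

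Under ATRA the largest difference between shTFEB and shScr cells lay in interferon-stimulated genes. IFI44 stood at 0.491 FPKM in shScr and 54.7 FPKM in shTFEB cells, the exonuclease gene ISG20 at 1.52 and 53.2 FPKM, OAS2, an oligoadenylate synthetase gene, at 10.9 and 208 FPKM, XAF1 at 0.882 and 30.1 FPKM and IFI44L at 0.335 and 24.8 FPKM. Of the 38 genes in the list 36 were at least 2-fold higher in shTFEB cells and none was lower; the other 2 were IFITM2 (log2 ratio 0.81) and IRF9 (0.35). The median of the list was 1.97, where the middle 95% of the random lists ran from 0.00 to 0.23. Abundant members took part: ISG15 stood at 61.0 and 529 FPKM and IFI6 at 175 and 1154 FPKM.

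**Figure D2:**
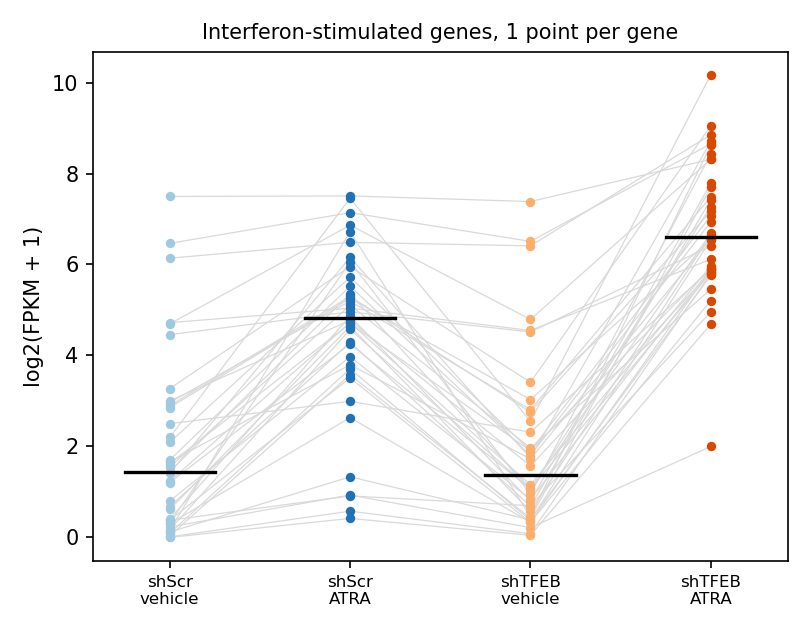
Each point is 1 of 38 interferon-stimulated genes, on a log2(FPKM + 1) scale, in the 4 groups (1 deposited value per gene and group); grey lines join the values of a gene and black bars mark the medians. The medians were 1.43 in shScr vehicle, 4.82 in shScr ATRA, 1.36 in shTFEB vehicle and 6.61 in shTFEB ATRA.

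Genes outside that list differed under ATRA as well. The remaining higher genes of the fixed ranking are listed at 0 in shScr ATRA (NUDT3, PPAN, GPN1 and PSMC3IP, with EEF1A1, which was not estimated there), and all 10 lower genes (SERF2, NAB2, EEF1E1, SNAPIN, IFT20, ADORA2A, TTLL3, SBDSP1, GLT8D1 and DBNDD2) are listed at 0 in shTFEB ATRA. In the ranking of genes above 0, made after the values were seen, SIGLEC1, a macrophage lectin gene that interferon also induces (0.803 and 21.8 FPKM), CLC (74.2 and 771 FPKM) and EPX (3.79 and 42.8 FPKM) were higher in shTFEB cells. Lower in shTFEB cells were the acute-phase genes ORM1 (23.5 and 2.51 FPKM) and ORM2, the growth factor gene BMP2 (20.8 and 3.06 FPKM), MARCKS, STRA6, which encodes a retinol transporter (27.9 and 6.10 FPKM), the formyl peptide receptor gene FPR2 (13.2 and 2.90 FPKM), ITGA6, S100A12 and TM4SF19.

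MYC stood at 25.6 FPKM in shScr ATRA and 54.6 FPKM in shTFEB ATRA. With it, the MYC and ribosome biogenesis list had a median of 0.60, above every random list, although only MYC and GNL3 passed the 2-fold mark. Neutrophil maturation genes went the other way (median −0.17, below every random list): FPR2, S100A12, S100A8 (685 and 219.9 FPKM), S100A9 (1119.6 and 379.8 FPKM) and the IgA receptor gene FCAR were at least 2-fold lower, and 1 member was higher. Some of this gap was present without ATRA. In shScr vehicle and the group labelled shTFEB vehicle, S100A9 stood at 11.2 and 2.08 FPKM and S100A8 at 1.73 and 0.652 FPKM. FPR2 stood at 0.113 and 0.0513 FPKM there, and S100A12 is listed at 0 in both. The lower ATRA levels of S100A9 and S100A8 are thus not by themselves a smaller response. Surface receptors and adhesion genes had a median of −0.21, with CD44 and CD74 lower. Promyelocyte genes held 5 higher members (PRG2 from 69.8 in shScr to 402 FPKM in shTFEB, PRG3, STAR, GATA2 and FLT3) and 1 lower (BPI), around a median of 0.06 that became −0.00 after upper-quartile rescaling. In the retinoic acid list the retinoid-degrading gene CYP26B1 was lower with STRA6, whereas TNFSF10 and CYP26A1 were higher, at 9.27 and 47.9 and at 0.871 and 4.33 FPKM. Immediate-early and heat shock genes had a median of −0.30 and a mean of 0.09, of opposite sign: IER3 was lower, but HMOX1, HSPH1, HSP90AA1, HSPA6 and HSPA1B were higher. GATA1 and ITGA2B were the 2 higher erythroid and megakaryocytic genes.

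Lysosome and autophagy genes differed little between the 2 ATRA groups. The lysosomal hydrolases had a median log2 ratio of −0.01, at the 2.34 percentile of the random lists, and CTSL alone passed the mark, at 6.70 and 16.3 FPKM. CTSD stood at 1830 and 1282 FPKM. Of the lysosomal membrane genes only LAMP3 passed it, at 1.87 and 16.3 FPKM (median 0.08). No V-ATPase gene did (0.05, below 0 after both rescalings at −0.02 and −0.04) and no autophagy gene (0.10); SQSTM1 stood at 164 and 115 FPKM. TFEB itself was the only MiT/TFE and mTORC1 gene past the mark. No member of the cell cycle (0.24), apoptosis (−0.01, mean 0.10), lipid (0.01), integrated stress response (−0.17) or histone lists (0.63) passed it, and the cholesterol list (0.30) held only TM7SF2, which is listed at 0 in both shScr groups. Chemokine and cytokine genes held 2 higher members, CCL8 and TNFSF13B, and 2 lower, CXCL8 and TNF.

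Under ATRA 295 genes were at least 2-fold higher and 175 at least 2-fold lower in shTFEB cells, 62.8% of the marked genes being higher. With a pseudocount of 5 FPKM the counts were 170 and 101, and the lower genes numbered 110 at a mean of at least 5 FPKM and 95 without genes listed at 0 in any group.

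**Figure D3:**
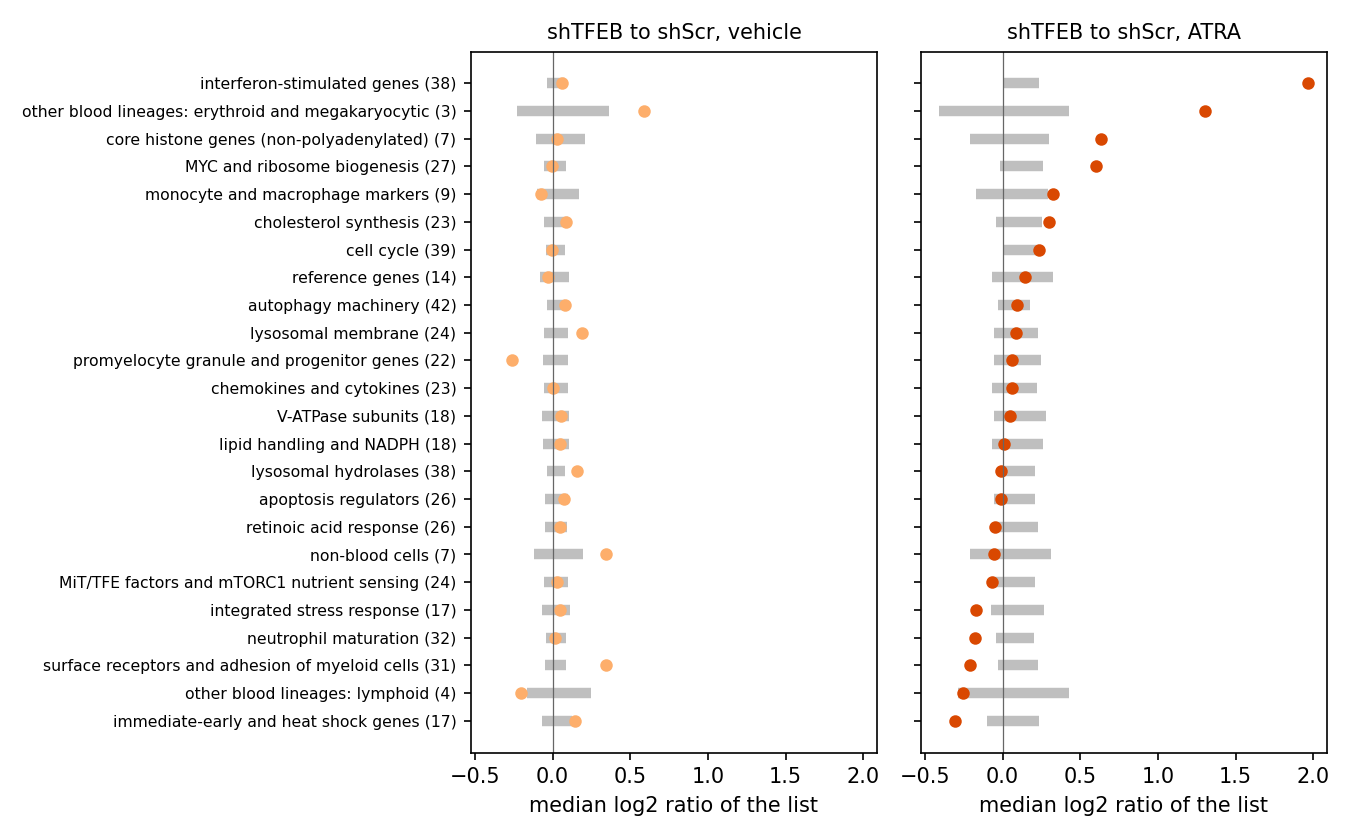
Points give the median log2 ratio of shTFEB to shScr cells (x axis) for each gene list, with the number of genes in brackets, under vehicle and under ATRA; grey bars give the middle 95% of 10000 random lists matched on expression. Interferon-stimulated genes lay at 0.06 under vehicle and 1.97 under ATRA, and the MYC and ribosome biogenesis genes at −0.01 and 0.60.

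Whether the ATRA response differed between the cell lines was addressed by the difference of the log2 responses, shTFEB minus shScr. The interferon-stimulated genes differed most: 35 of 38 had a response at least 2-fold larger in shTFEB cells, with a median difference of 1.96, with IFI44 (5.16), IFI44L (4.23), ISG20 (4.16) and XAF1 (3.73) among the largest. Without the added 1 FPKM the median difference was 1.88 over the 37 members above 0 in all groups, of which 35 had the larger response in shTFEB cells and 29 at least 2-fold larger (32 of 38 with 0.1 FPKM added). OAS2 (0.39), OAS1 (0.47), OAS3 (0.18) and UBE2L6 (−0.40) were among those that did not pass the mark without the added FPKM. The response was smaller in shTFEB cells for STRA6 (difference −2.51), CCL2 (−2.26), ORM1 (−2.55), IER3 (−2.22), FPR2 (−1.79) and the integrin gene ITGAM (−1.66). CCL2 and ITGAM started from a higher level in the group labelled shTFEB vehicle. MYC and ribosome biogenesis genes fell less in shTFEB cells (median difference 0.60, where genes lowered at least 2-fold in general differed by 0.28), with MYC and GNL3 past the mark at 1.10 and 1.03. Promyelocyte genes had a median difference of 0.55, but they started from a lower level in the group labelled shTFEB vehicle (median −0.26) and stood at a median of 0.06 under ATRA. In that list PRG2 (2.01) and PRG3 (1.73) passed the mark upwards and BPI (−1.21) downwards, BPI only with the added 1 FPKM (−0.43 with 0.1 FPKM). Neutrophil maturation genes had a median difference of −0.26, with 6 members past the mark downwards and 2 upwards, and surface receptors one of −0.40, which stood at 0.34 under vehicle and −0.21 under ATRA, beside −0.16 for genes raised at least 2-fold in general. The retinoic acid response list lay close to that general value, at −0.19 (mean −0.04), with 2 members past the mark in each direction.

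The lysosomal hydrolases had a median difference of −0.15 (0.16 under vehicle, −0.01 under ATRA), below every random list matched on expression, and no member past the 2-fold mark. Genes raised at least 2-fold in general differed by −0.16, and 22 of the 38 hydrolases had risen in shScr cells. SQSTM1 (−0.81) had the furthest difference of the autophagy genes, which had none past it either (median −0.02). The V-ATPase median was −0.04, and the lysosomal membrane median of 0.00 became −0.10 after upper-quartile rescaling. Only TFEB (−1.21) and DDIT4 (−1.16) passed the mark in the MiT/TFE and mTORC1 list. By the fixed ranking, 8 of the 10 largest upward differences and all 10 downward ones belong to genes listed at 0 in some group, such as SLMO2-ATP5E, NUDT3, SERF2 and NAB2, so the genes above come from the lists and from the ranking of genes above 0.

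Across genes, which are not independent replicates, the 2 responses had a Pearson r of 0.805 and a Spearman rho of 0.909, or 0.937 and 0.936 over the 10733 genes above 0 in all groups. Of the genes past the mark 1060 rose in both cell lines, where independent lists would share 159, and 1002 fell in both, against 176. A further 324 rose and 674 fell in shScr cells alone, and 210 rose and 157 fell in shTFEB cells alone. Among the 1195 genes whose mean response was at least 2-fold upwards 63.0% had the smaller response in shTFEB cells, and among the 1262 downwards genes 79.5% did, with median differences of −0.16 and 0.28. In all, 268 genes had a difference of at least 1 upwards and 206 downwards. Without genes listed at 0 in any group these were 174 and 97, without small RNA symbols 126 were downwards, and a pseudocount of 5 FPKM (126), a mean of at least 5 FPKM (127) and intervals that do not overlap (130) also lowered the second count.

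**Figure D4:**
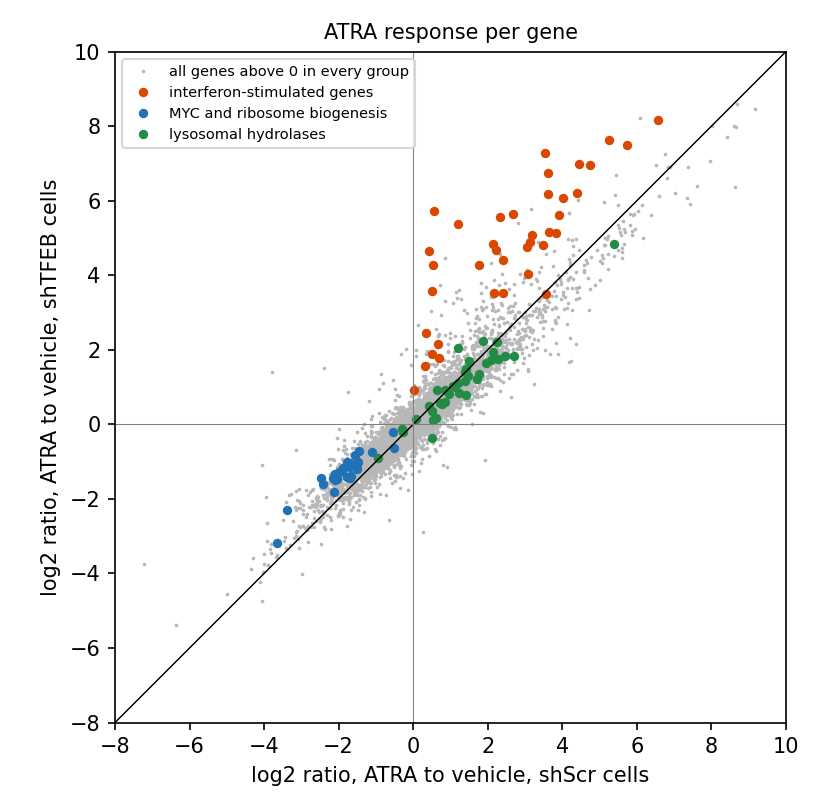
Each grey point is a gene above 0 in all 4 groups, with its log2 ratio of ATRA to vehicle in shScr cells (x axis) and in shTFEB cells (y axis). The diagonal marks equal responses. Members of 3 gene lists are coloured, also where listed at 0 in a group, such as IFI44L in shScr vehicle. Interferon-stimulated genes lie above the diagonal except IRF9, at 3.56 and 3.49, and MYC lies at −3.39 and −2.29.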

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

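All tests of explanations in this part were chosen after the results were seen. Across the 2 cell lines, 21 genes were at least 2-fold apart under ATRA in opposite directions. Of these, 19 were small RNA symbols, and the other 2, SERF2 and LCTL, are listed at 0 in groups of both cell lines. Only 2 of the 21, the small RNAs RMRP and RPPH1, were above 0 in all 4 groups. With 1 value per group the difference was not tested.

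Assembled models without a gene symbol stood outside the gene comparisons. Of 712 such models with a mean of at least 1 FPKM, 142 were at least 2-fold higher under ATRA in shScr cells, 79 of them also in shTFEB cells, and 83 were lower in shScr cells. Among the models above 0 in all 4 groups, the largest rise in shScr cells belonged to one on hg19 chromosome 16 (55461463 to 55470523). It went from 0.148 to 33.4 FPKM in shScr cells and from 0.253 to 14.6 FPKM in shTFEB cells.

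Interferon-stimulated genes were higher in shTFEB than in shScr cells under ATRA. A difference in scale is excluded as the whole cause, since the median log2 ratio stayed at 1.89 after upper-quartile rescaling. For a response already present without ATRA, members were split by their vehicle values. The 23 members with at least 1 FPKM in a vehicle group had a median log2 ratio under vehicle, with no FPKM added, of 0.0613. As a set they thus showed no vehicle difference of the size seen under ATRA (UBE2L6, at 0.122 and 1.08 FPKM, is an exception). A weaker response is not excluded, because the split rests on the same vehicle values. For the 14 members below 1 FPKM that median was 1.12, against 0.15 for 368 other genes as low, so a response present without ATRA may account for part of their difference. A larger ATRA response of shTFEB cells as a whole is excluded too: the other 1160 genes raised by ATRA had a median difference of −0.18, whereas 37 of the 38 list members, all but IRF9, responded more in shTFEB cells (35 of 37 with no FPKM added). The lower TFEB mRNA of these cells may be the cause, as may the hairpin itself or a difference between the cultures, and with 1 shTFEB line none of these was tested.

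Genes at 0 in a group and at 5 FPKM or more in another numbered 109, without small RNAs and failed estimates. Another expressed model lay over the locus in 78.0% of them, against 14.7% of 8628 genes above 0 in all groups, so fragments given to an overlapping model are a candidate explanation. Too few sequenced fragments could not be tested on this set: the highest FPKM of its middle gene is worth 569.9 fragments in a 950-base model, but the choice of genes from 5 FPKM fixes a high value. A true loss of the transcript was not tested gene by gene.

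EPX, HDC and CLC, eosinophil and basophil genes picked after their values were seen, were higher in the group labelled shTFEB vehicle. A separate list of such genes was written without those 3, and 13 of its 25 members were compared. Of these, GATA1, IL1RL1 and GATA2 passed the mark, 10 did not, and RNASE3 stood lower, at 7.83 against 16.2 FPKM. A fall of TFEB mRNA like that under ATRA was not seen, the lowest ratio the deposited bounds allow being 0.731, but these bounds are not confidence intervals and it stays open. A difference between the cultures that ATRA left in place, at least in sign, may account for it: of 93 genes past 2-fold under vehicle and above 0 in all groups, 84.9% kept their sign under ATRA and 34 were still past 2-fold, while 63.2% of all genes above 0, most of them below the 2-fold mark, had the same sign. A lasting effect of the hairpin would keep the sign in the same way, so these shares cannot tell it from a culture difference. Whether the shTFEB culture held a share of eosinophil-lineage cells cannot be told apart from a change within cells. Of RNASE2, RNASE3, PRG2 and CLC only 1, CLC, was at least 2-fold higher. CLC had been picked for its high value, so its pass was fixed beforehand and lends this explanation no weight. The other 3 did not pass the mark. An effect of the hairpin on other transcripts was not tested.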

How the results depend on the processing

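Leaving out small RNA symbols, failed estimates or genes listed at 0, and the interval midpoints, were chosen after seeing the data. Of 602 values of named genes, 383 were past the mark, and none of these changed sign in the alternatives that held them. Sign changes of values below the mark were not counted. A pseudocount of 5 FPKM took 60 of the 383 below the mark. With that pseudocount, which draws ratios of low values towards 0 by construction, ATRA gave 873 higher and 949 lower genes in shScr cells and 795 and 582 in shTFEB cells; shTFEB against shScr gave 70 and 48 under vehicle and 170 and 101 under ATRA, and the difference had 126 downwards. A pseudocount of 0.1 FPKM gave 211 higher genes under vehicle. With a mean of at least 5 FPKM, which leaves fewer genes, the vehicle comparison gave 67 and 52, ATRA 110 lower genes and the difference 127 downwards. Without small RNA symbols these were 67 and 45 under vehicle and 126 downwards in the difference. Without genes listed at 0 in any group they were 56 and 37 under vehicle, 95 lower under ATRA, and 174 upwards and 97 downwards in the difference. Where intervals had not to overlap, 72 and 50 were left under vehicle and 130 downwards in the difference. TFEB in shScr ATRA became 21.0 FPKM under median-of-ratios rescaling, which divides that group by 0.921. The medians of the added eosinophil, basophil and mast cell list under ATRA went from 0.49 in shScr and 0.87 in shTFEB cells to −2.10 and −1.27 with a mean of at least 5 FPKM, which leaves 6 of its 13 genes, and some list medians near 0 changed sign under rescaling. The other counts of genes past the mark stayed within 1.5 times the reported ones. No paired analysis was possible because the labels number the samples 1 and 2 in each group but the tables give 1 value per group; for the same reason the replicate block, leaving out each sample, the fit on the compared groups alone and the count-based tools were not run. Depth limits values near 0.0189 FPKM, the worth of 1 fragment in a 950-base model at the lowest depth.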

Other observations

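The genes in this part were chosen after their values were seen. Among metallothionein genes, MT2A was at 126 FPKM in shScr vehicle, 99.8 in shScr ATRA, 176 in the group labelled shTFEB vehicle, where TFEB mRNA was not lower, and 655 in shTFEB ATRA, 6.56-fold higher than in shScr cells under ATRA. MT1E stood at 14.2, 10.5, 46.4 and 57.2 FPKM in the same order, and MT1G at 18.2, 13.5, 43.4 and 47.3 FPKM. MT2A and MT1X did not pass the mark under vehicle (log2 ratios of the group labelled shTFEB to shScr cells 0.47 and 0.66), and MT1F did not under ATRA (0.66). The potassium channel gene KCNH2 went from 33.8 to 2.27 FPKM with ATRA in shScr cells and from 95.6 to 21.7 FPKM in shTFEB cells. In the list of eosinophil, basophil and mast cell genes, 13 of 25 members were compared. The median log2 ratio to shScr cells was 0.50 in the group labelled shTFEB vehicle, with GATA1, IL1RL1 and GATA2 past the mark. It was 0.95 in shTFEB ATRA, with PRG2, PRG3, SIGLEC8, GATA1, GATA2 and PTGDR2 past it. Both medians lay above every random list, which is no independent support because the list was written after the values were seen. Its ATRA medians were 0.49 in shScr and 0.87 in shTFEB cells, and −2.10 and −1.27 with a mean of at least 5 FPKM.

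Genes around the interferon response were examined beside it. The interferon gene IFNB1 stood at 0.0202 FPKM in shScr vehicle, 0.135 in shScr ATRA and 0.754 in shTFEB ATRA, and is listed at 0 in the group labelled shTFEB vehicle, while IFNG is listed at 0 in all 4 groups. IFNA1 stood at 0.223 FPKM in shScr ATRA and 0.814 FPKM in shTFEB ATRA. Among genes of nucleic acid sensing pathways, EIF2AK2 stood at 26.3 and 66.4 FPKM and TLR3 at 0.618 and 3.38 FPKM in the 2 ATRA groups, whereas STING1 was at 212 in shScr and 157 FPKM in shTFEB cells.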
